A study of Caenorhabditis elegans with 2 samples.

How the data were processed

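The measurement was chromatin immunoprecipitation followed by sequencing (ChIP-seq) of EFL-1, a worm member of the E2F family of transcription factors, in whole young adult *Caenorhabditis elegans* of mixed sex. Per the labels, the worms were of strain YL445, which carries a transgene made of the *pie-1* promoter, EFL-1 fused to GFP and FLAG, the *efl-1* 3′ untranslated region and a rescuing *unc-119* fragment, in an *unc-119* mutant background. The labels name efl-1 as the target of the antibody in one field and the eGFP fusion in another, so whether untagged EFL-1 was also precipitated is unsettled here. There was 1 group of 2 samples, which the labels number as biological replicates 1 and 2, and the size range given for the fragments was 150 to 350. A control library and worms without the transgene were not analysed here.

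The deposited files were peak lists with 10 columns, read as the narrowPeak format that the description deposited with each sample names. Per that description, the authors made a relaxed list of peaks and background for each replicate from its own alignments against a control, a pooled relaxed list from the alignments of both replicates, and an optimal list that keeps the pooled peaks passing an irreproducible discovery rate (IDR) threshold, in builds ce10 and ce11. Column 7 of each deposited list holds the authors' signal value per region, which is never negative and whose scale is not stated. Column 9 holds a −log10 q-value per region in the deposited lists, and column 10 the offset of the summit from the start of the region. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The signal value is the authors' own and was used to rank, filter and describe regions within a list and to compare ranks between replicates. Its level in each replicate is given as a description and was not tested. Each relaxed list held 30000 regions, a fixed length, so list length carries no information on enrichment. Read totals were not used here and sequencing depth is therefore unknown. No interval in the text rests on depth. The optimal list was tested against the pooled list and equalled its 2498 regions of highest signal in ce11 and its 2542 regions of highest signal in ce10. It was therefore ranked by the pooled signal.

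Positions are given in ce11, counted from 1. Genes came from Ensembl release 115 on WBcel235 and bases from the RefSeq copy of WBcel235, whose description equates its coordinates with ce11, and all ce11 regions lay inside its chromosome lengths. The ce10 lists were compared by counts and values only, with no conversion of coordinates. A protein-coding gene was called bound where the summit of an optimal peak lay from 1000 bp upstream to 200 bp downstream of the annotated 5′ end of any of its transcripts. A summit could therefore be assigned to several genes, and annotated 5′ ends in the worm are often trans-splice sites or the starts of genes inside operons, which this window misses. Promoter, coding exon, untranslated or other exon, intron and intergenic classes were given in that order of priority.

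Replicates were compared through the overlap of optimal peaks, by at least 1 bp, with each replicate's relaxed list and with its 2498 highest regions, called its top regions below. Location was tested with a two-sided permutation test against 1000 sets of random positions on the same chromosomes. Gene lists, chromosome X against the autosomes and the middle of each autosome (1 of 3 equal parts) against its arms were tested with two-sided Fisher's exact tests over the 19985 protein-coding genes, with Benjamini-Hochberg adjustment over the 21 lists. The lists were fixed before the data were examined and held 702 names, of which 3 matched no gene symbol. The ribosomal protein and histone lists were fixed as symbol patterns and filled from the annotation, so their 78 and 50 names could not fail to match. The E2F core TTSSCGC (S is C or G) was searched on both strands within 50 bp of each summit, in windows of 101 bp, and in windows of the same length centred 500 bp to either side. The same was done for the 179 other orders of its units, for TTTSSCGC, for TTYGAA (Y is C or T), which resembles the cell cycle homology region bound by the DREAM complex, and for a GAGA repeat. Intervals are 95% Wilson intervals of shares. P-values cover the sampling of genes or windows and not the spread between replicates, since the tests were made within pooled lists. Neighbouring genes can share a peak and are not fully independent.

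Genes named in the text were the genes of the 15 optimal peaks with the highest signal, up to 4 bound members with the highest signal and up to 2 unbound members of each list, every member of the DREAM and E2F list, and *pie-1*, *efl-1* and *unc-119*. Any other gene is said to be chosen after its values were seen. Alternatives planned before the data were examined were each replicate's own top regions, the upper 50% of optimal peaks by signal, other gene windows, the nearest gene only, a background of genes with a pooled relaxed summit, other motif windows and controls, other overlap rules and build ce10. A run without mitochondrial peaks and a run with the optimal peaks found in the top regions of both replicates were chosen after seeing the data. The scripts ran on Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. On simulated data, the list test recovered an enriched list of 40 genes in 99 of 100 runs and called 5 of 2100 unchanged lists, the gene window recovered 200 of 200 planted peaks, and the motif search recovered 1187 of 1187 planted summits. The planted peaks lay inside the window and the planted cores were exact, so both of these outcomes were fixed and check the code only. Simulated genes were bound independently, without the shared peaks of the real data. In the simulated locations, 1 of 20 random peak sets had a class called.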

Results

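EFL-1 was mapped by ChIP-seq in whole young adult *C. elegans* carrying an EFL-1::GFP transgene driven by the *pie-1* promoter, which is known to be active in the germline. The series held 1 group with 2 biological replicates and no comparison group. The comparisons were therefore made within the peak lists, between the replicates, and against genes, positions and sequences elsewhere in the genome. Sequencing depth was unknown.

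The strongest EFL-1::GFP peaks lay at *rib-2* and *tbb-1*, *hcp-1*, *rpl-3* and *pie-1*. The peak with the highest signal value, 1564, lay on chromosome III at 10742463 to 10742887 (ce11), in intergenic DNA, with its summit at -123 bp from the 5′ end of *rib-2* (WBGene00004361), a gene of heparan sulfate synthesis, and at -255 bp from that of *tbb-1* (WBGene00006536), which encodes a β-tubulin. It ranked 9 in replicate 1 and 1 in replicate 2. The peak at *hcp-1* (WBGene00001829), a centromere protein gene, lay on chromosome V at 6593703 to 6594096 and had a signal value of 1405. *hcp-3*, which encodes the centromeric histone H3 variant, *sgo-1*, which encodes a shugoshin, and *nasp-2*, a histone chaperone gene, had signal values of 1133, 1221 and 1242. Among egg and polarity genes, *par-3* had 1134 and *cpg-2*, which encodes an eggshell proteoglycan, had 1109. The germline helicase gene *glh-2* shared its peak, with a signal of 1069, with *C55B7.11*, and the replicative helicase gene *mcm-2* had 1020. The other peaks among the 15 highest belonged to *rpl-3* (1306), *pie-1* (1302), *cdc-48.1* (1209), *T21B10.3* (1075), the pair *Y53F4B.11* and *Y53F4B.9* (1173), and a mitochondrial peak assigned to *COX3* (1148), for which the promoter window has no meaning. Of these, *rpl-3*, *cdc-48.1* and *COX3* had no E2F core within 50 bp of the summit.

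The authors' optimal list held 2498 peaks in ce11, and the ce10 list held 2542. Peaks had a median width of 336 bp and together covered 0.705% of the genome. Signal values ran from 34.9 to 1564, with a median of 71.1.

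How far the replicates shared these peaks was examined. Of replicate 1's 2498 top regions, 1815 (72.7%, 95% interval 70.9 to 74.4) were overlapped by those of replicate 2. The optimal list was built from both replicates, so its overlap with each is raised by selection. Optimal peaks were overlapped by the top regions of replicate 1 in 1971 cases (78.9%, 95% interval 77.3 to 80.5) and by those of replicate 2 in 2301 cases (92.1%, 91.0 to 93.1). Both replicates held 1822 of them (72.9%) among their top regions. Random draws of as many regions from the relaxed lists of replicates 1 and 2 overlapped 8.62% and 9.22%. The whole relaxed lists overlapped 97.7% and 99.96% of optimal peaks. The shares of the random draws were therefore set mainly by the fraction of each list that was drawn. They give no chance level for the sharing of peaks between replicates. Of the 500 lowest peaks, 43.2% were among the top regions of replicate 1 and 65.6% among those of replicate 2. Across the 2440 peaks present in both relaxed lists, the signal values had a Spearman rho of 0.785, a description across peaks, which are not independent replicates. The median signal was 21.9 in replicate 1 and 53.9 in replicate 2, levels left untested because depth was unknown. Requiring a reciprocal overlap of 50% left 64.8% for replicate 1.

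**Figure D1:**
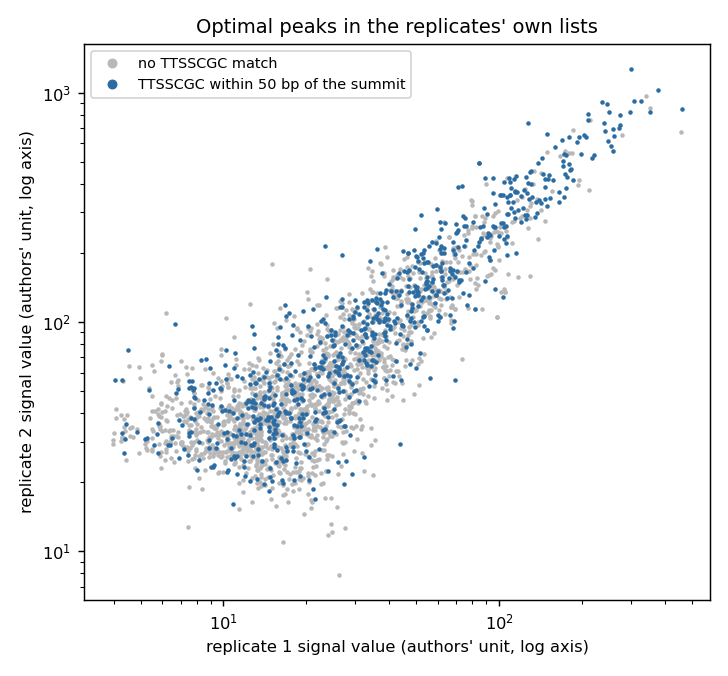
Signal values of 2440 optimal peaks in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis), in the authors' unit, with one point per peak and blue points for peaks with the E2F core within 50 bp of the summit. Strong peaks line up between replicates (rho 0.785 over all points), and the scatter widens at low signal.

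EFL-1::GFP peaks were concentrated just upstream of genes. Summits fell in promoter windows in 1908 of 2498 peaks (76.4%), against 26.9% ± 0.871 (SD over 1000 sets) of random positions. Coding exons held 0.761% of summits against 19.4%, introns 7.01% against 28.5% and intergenic DNA 11.8% against 19.9% (adjusted p = 0.0025 for each of these classes, from the smallest p the permutation test can give, 0.002). Untranslated or other exons held 4.0% against 5.25% (adjusted p = 0.0040, permutation test), a deficit that was not past the threshold in either replicate's own top regions (adjusted p = 0.24 and 0.22). Without the promoter class, 69.98% of summits lay in intergenic DNA, 16.1% in introns, 11.8% in untranslated or other exons and 2.12% in coding exons. The median summit lay at -188 bp from the nearest 5′ end. Of the 1908 promoter summits, 1198 fell in the window of 1 gene and 710 in those of 2 or more, and 668 (35.0%) served genes on both strands.

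Bound genes were scarce on chromosome X. Of 2731 protein-coding genes on X, 72 were bound (2.64%, 95% interval 2.1 to 3.31), against 2431 of 17242 on the autosomes (14.1%, 13.6 to 14.6), an odds ratio of 0.165 (Fisher's exact test, p = 7.7e-85). Among the nuclear chromosomes, III and I had the highest shares, with 21.2% and 19.7% of genes bound. Chromosomes II and IV had 14.1% and 12.3%, and V had 8.27%. Peak density on these chromosomes followed the same order, from 40.1 peaks per Mb on III to 5.53 on X. Within the autosomes, 998 of 6568 genes in the centres (15.2%) and 1433 of 10674 in the arms (13.4%) were bound, an odds ratio of 1.16 (Fisher's exact test, p = 0.00127). The difference between centres and arms was not past the threshold among genes with any pooled relaxed summit (odds ratio 1.09, exact p = 0.0971).

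**Figure D2:**
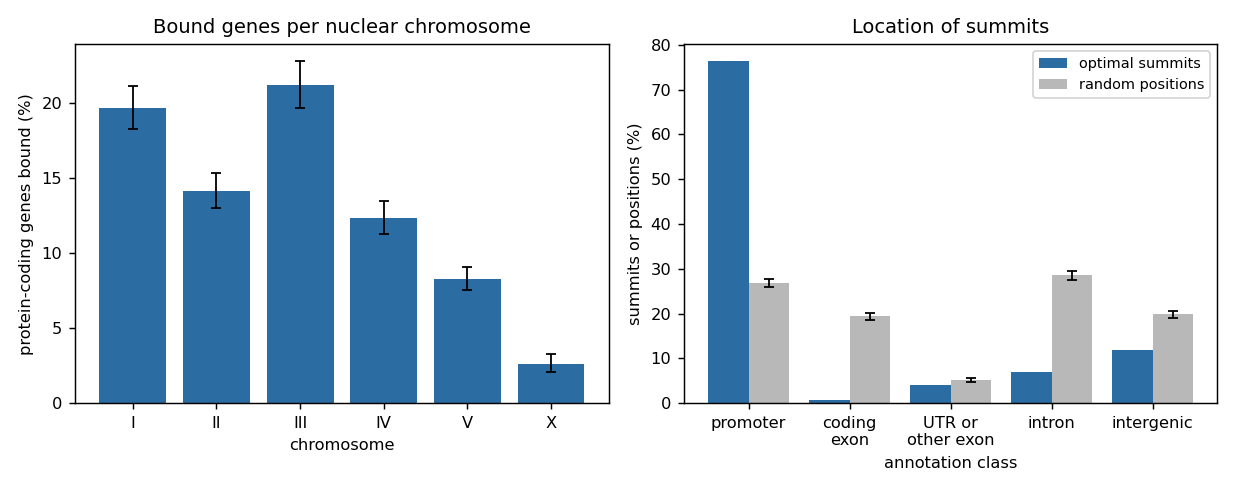
Left, percent of protein-coding genes bound on each nuclear chromosome, with 95% Wilson intervals; right, percent of the 2498 optimal summits (blue) and of random positions (grey, mean with SD over 1000 sets) in each annotation class. Chromosome X stands at 2.64% and III at 21.2%, and promoters hold 76.4% of summits against 26.9% of random positions.

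In all, 2513 of 19985 protein-coding genes (12.6%) were bound. Of the 21 gene lists fixed beforehand, 12 held more bound genes than the remaining genes did and 2 held fewer, at an adjusted p under 0.05 by Fisher's exact test, whose adjusted p-values are called exact below. The count of lists with fewer was 0 in 6 of the 9 alternatives and 3 with the 2000 bp window, while 11 to 13 lists held more.

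Genes that copy DNA and divide the cell were bound in most cases. Of 39 DNA replication genes, 34 were bound (87.2%, exact adjusted p = 4.2e-25), and 24 (61.5%) with each summit given to its nearest gene only. The 34 bound genes included *mcm-2*, the topoisomerase gene *top-2* (signal 738), *pcn-1*, which encodes the sliding clamp PCNA (605), and *rpa-1*, which encodes a single-strand DNA binding protein (572). Each of these peaks had an E2F core within 50 bp of its summit. The *pcn-1* peak lay on chromosome IV at 4049502 to 4049863 in intergenic DNA, with its summit at -236 bp. The origin recognition genes *orc-2* and *orc-4* were not bound. Of 64 mitosis and cell cycle genes, 54 were bound (84.4%, exact adjusted p = 6.2e-38), and 42 (65.6%) counting the nearest gene only. The highest were *hcp-3*, the kinetochore genes *rod-1* (975) and *hcp-4* (864), and the kinesin gene *klp-7* (870). *cdk-4* and *cyd-1*, which encode the G1 kinase and its cyclin, were not bound. DNA repair genes were bound in 22 of 41 cases (53.7%, exact adjusted p = 9.4e-10), with *fcd-2* (463), *atm-1* (330), *polh-1* (255) and *xpf-1* (203) highest and *brd-1* and *brc-2* unbound.

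Oocyte, meiotic and germ granule genes were also bound in most cases. Of 40 oocyte and early embryo genes, 32 were bound (80%, exact adjusted p = 1.9e-21), led by *pie-1*, *par-3*, *mex-1* (994), a gene for an RNA-binding protein of the embryo, and the yolk receptor gene *rme-2* (959). *mbk-2* and *puf-6* were not bound. Genes of meiotic chromosomes were bound in 19 of 31 cases (61.3%, exact adjusted p = 8.0e-10). Their share fell to 14 of 31 (45.2%, against 9.85% of other genes) with peaks in the top regions of both replicates. In the upper 50% of peaks it was 10 of 31 (32.3%, against 7.38%). The highest were the meiotic cohesin genes *rec-8* (725), *coh-4* (692) and *coh-3* (462), followed by *pch-2* (192), and none of these peaks had an E2F core within 50 bp of the summit. The *rec-8* peak was also that of *mex-5* in the oocyte list, and the *coh-3* peak that of *bmk-1* in the mitosis list. *mex-5* and *bmk-1* were chosen after their values were seen. *him-1* and *him-8* were not bound. Germ granule and germline RNA regulators were bound in 16 of 26 cases (61.5%, exact adjusted p = 1.5e-08), with *glh-2*, *daz-1* (428), *lip-1* (340) and the Argonaute gene *csr-1* (339) highest and *gld-1* and *glh-1* unbound. In the upper 50% of peaks 11 of 26 (42.3%) were bound. Sperm genes were bound in 0 of 26 cases, *spe-4* and *spe-6* among them (95% upper bound 12.9%, adjusted p = 0.0887, Fisher's exact test). Of 9 alternatives only the 2000 bp window took them past the threshold (exact adjusted p from 0.0354 there to 0.416). The highest p was that of replicate 1's own top regions, where 1 of 26 sperm genes was bound.

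EFL-1::GFP also lay at genes of its own complex. In the DREAM complex and E2F list, 6 of 10 genes were bound (60%, adjusted p = 9.2e-04, Fisher's exact test). With each summit given to its nearest gene only, 4 of 10 were bound (40%, exact adjusted p = 0.0166). The peak of *lin-9* (WBGene00002998, chromosome III at 8904030 to 8904432, intergenic) had a signal of 628, that of *lin-53* 535, that of the retinoblastoma homologue *lin-35* (WBGene00003020, chromosome I at 5807369 to 5807708, intergenic) 333 and that of *lin-54* 318. *lin-52* had 137. *dpl-1*, which encodes the DP partner of EFL-1, had 58.6 and ranked 8873 in replicate 1 against 1264 in replicate 2. *efl-1*, *efl-2*, *efl-3* and *lin-37* were not bound. Chromatin and synMuv B genes were bound in 11 of 26 cases (42.3%, exact adjusted p = 2.9e-04), with the Polycomb genes *mes-2* (406) and *mes-6* (319), *set-2* (307) and *lin-61* (245) highest and *lin-13* and *hpl-1* unbound. In replicate 1's own top regions the share was 7 of 26 (26.9%, exact adjusted p = 0.0477), as it was among peaks in the top regions of both replicates (exact adjusted p = 0.0197). The call was lost among genes with any pooled relaxed summit (47.8% against 28.1%, exact adjusted p = 0.104), the highest p of the 9 alternatives, which ran from 4.6e-05.

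Housekeeping groups were bound as well. Of 78 ribosomal protein genes, 65 were bound through 62 peaks (83.3%, exact adjusted p = 1.2e-44), and 39 (50%) with each summit given to its nearest gene only. The *rpl-3* peak (WBGene00004414) lay on chromosome III at 3867382 to 3867759 in intergenic DNA, with *rpl-35* (932), *rps-12* (357) and *rpl-20* (341) next and *rpl-10* and *rpl-11.1* unbound. Proteasome genes were bound in 21 of 31 cases (67.7%, exact adjusted p = 6.0e-12), led by *rpn-6.1* (672), *pas-6* (524), *rpn-11* (282) and *rpn-2* (237), with *pas-1* and *pas-2* unbound. Splicing genes were bound in 16 of 30 cases (53.3%, exact adjusted p = 2.2e-07), 10 of them counting the nearest gene only, led by *rsp-6* (332), *rsp-3* (218), *snr-6* (190) and *snr-2* (180), with *snr-5* and *snr-7* unbound. Genes of the mitochondrial respiratory chain were bound in 14 of 31 cases (45.2%, exact adjusted p = 1.6e-05), led by *cox-5B* (485), *cox-5A* (383), *cox-6B* (210) and *sdhd-1* (123), with *nuo-2* and *nuo-3* unbound.

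Genes of differentiated body tissues were seldom bound. The fusion was driven by the *pie-1* promoter, known to be active in the germline, and its presence in these tissues was not examined here. Absence of binding and absence of the fusion there cannot be told apart. None of 30 intestine genes (*vit-1* and *vit-2*, which encode yolk proteins, among them) and none of 31 hypodermis and cuticle genes (*rol-6* and *rol-8* among them) was bound (95% upper bounds 11.35% and 11.03%, adjusted p = 0.0408 for both, Fisher's exact test). None of them was bound in any of the 9 alternatives, but the p-values lay near the threshold. The intestine call was lost in 7 (exact adjusted p from 0.0156 to 0.386 over all 9) and the cuticle call in 6 (exact adjusted p from 0.0156 to 0.251), each replicate's own top regions among them for intestine and replicate 1's for cuticle. Muscle genes were bound in 2 of 32 cases (adjusted p = 0.493, Fisher's exact test), namely *unc-45* (185) and *unc-112* (41.1), with *unc-54* and *myo-1* unbound. In replicate 1's own top regions 1 of 32 was bound (exact adjusted p = 0.224). Neuron genes were bound in 2 of 43 cases (adjusted p = 0.202, Fisher's exact test), namely *tdc-1* (178) and *unc-119* (38.4), with *unc-17* and *cha-1* unbound. In replicate 1's own top regions 1 of 43 was bound (exact adjusted p = 0.0782). The *unc-119* peak was absent from replicate 1's relaxed list, and *unc-119* is also part of the transgene.

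The remaining lists did not pass the threshold by Fisher's exact test. RAS and MAP kinase genes were bound in 1 of 16 cases (exact adjusted p = 0.779), which was *gap-3* (105), with *let-60* and *lin-45* unbound. Apoptosis genes were bound in 3 of 21 cases (exact adjusted p = 0.779), namely the p53 homologue *cep-1* (111.6), *egl-1* (46.4) and *psr-1* (45.7), with *ced-1* and *ced-2* unbound. Genes of the histone list were bound in 6 of 50 cases (exact adjusted p = 1), including *his-67* and *his-68*, which shared a peak (98.1), *his-72* (80.7) and *his-74* (70.9), and *his-1* and *his-12* were not bound. That list kept 1 gene per symbol and so was not complete. In the whole *his* family of 72 protein-coding genes, 7 were bound (9.72%). For the genes of the transgene parts, 2 of 3 were bound (exact adjusted p = 0.0608), and the list passed the threshold with the 500 bp window and with the nearest gene only (exact adjusted p from 0.0383 to 0.387 over 9 alternatives). The share fell to 1 of 3 in replicate 1's own top regions, in the upper 50% of peaks and with peaks in the top regions of both replicates.

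**Figure D3:**
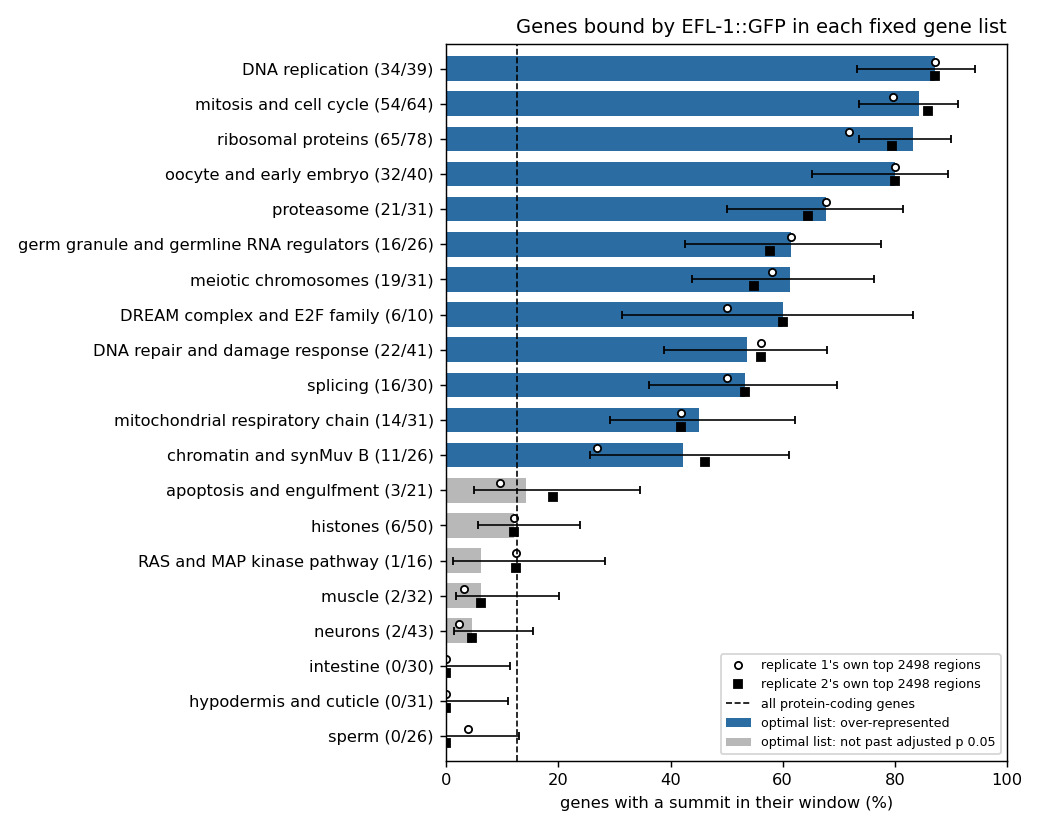
Percent of the genes of each list with an optimal summit in their window (bars, with 95% Wilson intervals and bound over total counts), with the same percent from each replicate's own top regions (open circles replicate 1, filled squares replicate 2) and the percent over all protein-coding genes (dashed line, 12.6%). DNA replication (34/39) and mitosis (54/64) stand at the top, and intestine, cuticle and sperm lists at 0.

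Of the 3 genes that lend parts to the transgene, 2 had peaks. *pie-1* (WBGene00004027) had a peak on chromosome III at 12426580 to 12426929, with a signal of 1302 and the highest rank of all in replicate 1 (rank 9 in replicate 2), in intergenic DNA at -125 bp from its 5′ end and with an E2F core. A weaker peak lay in an intron of *pie-1* at 12427971 to 12428306, with a signal of 39.6, rank 1480 in replicate 1 and rank 3625 in replicate 2. A peak beyond the 3′ end of *pie-1*, at 12429783 to 12429994 with a signal of 190, was that of *snr-6*. Since the transgene also holds the *pie-1* promoter, the peak lists do not separate the chromosomal copy from the transgene. Inside *unc-119* (WBGene00006843), 4 optimal peaks had their summits between positions 10904654 and 10907926 of chromosome III, 2 in introns and 2 in coding exons. Replicate 2 held all 4 in its relaxed list, and replicate 1 held 1 of them. *efl-1* had 0 optimal peaks in its gene body.

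The E2F core was the sequence feature examined at the summits. TTSSCGC lay within 50 bp of 768 of 2498 summits (30.7%, 95% interval 28.97 to 32.6) and in 205 of 4996 flanking windows (4.10%), an odds ratio of 10.4 (Fisher's exact test, p = 9.3e-218). Among the 180 orders of its units it had the highest odds ratio. The 179 rearranged motifs had a median of 1.64 and a maximum of 8.97. The longer TTTSSCGC lay at 17.1% of summits and 2.1% of flanks (odds ratio 9.63). TTYGAA lay at 38.8% of summits and 29.4% of flanks (odds ratio 1.52, p = 3.8e-16, Fisher's exact test), and the GAGA repeat at 1.84% and 0.821% (odds ratio 2.27). The excess of TTYGAA is one over flanks at 500 bp and did not centre on the summit, as its positions below show. Rearranged orders were tested for TTSSCGC only. Matches to TTYGAA were more frequent at summits with the E2F core (46.2%) than without (35.5%, odds ratio 1.56, p = 6.0e-07, Fisher's exact test).

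The share of peaks with the E2F core fell with rank. It was 52.8% (48.4 to 57.1) in the 500 strongest peaks, 34.4% in the next 500 and 17.9% (14.8 to 21.5) in the last 498, while flanks stayed between 3.40% and 4.80%. Peaks with the core had a median signal of 109 and were in the top regions of both replicates in 81.6% of cases. Peaks without it had 64.1 and 69.1%. The core was present at 67.6% of the peaks of DNA replication genes, 59.4% of oocyte and early embryo peaks and 57.4% of mitosis peaks. The bound genes of these lists had strong peaks, with median ranks of 279.5, 111 and 366. Against peaks of like rank, a comparison chosen after the data were seen, none of the 12 lists tested had a higher share past the threshold. The core was present at 9.68% (6 of 62) of ribosomal protein gene peaks, 10.5% (2 of 19) of meiotic peaks and 0 of 14 respiratory chain peaks (95% upper bound 21.5%).

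**Figure D4:**
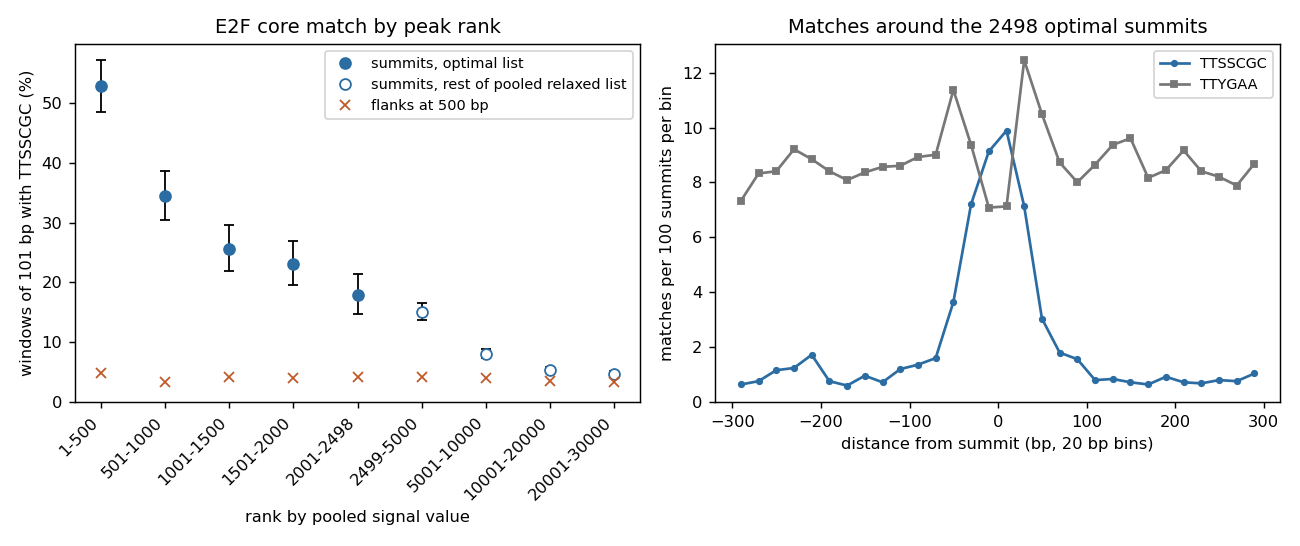
Left, percent of 101 bp windows with TTSSCGC at summits of the pooled list by rank of signal value (filled points optimal list, open points remaining relaxed regions, 95% Wilson intervals) and in flanks at 500 bp (crosses); right, matches to TTSSCGC and TTYGAA per 100 optimal summits in bins of 20 bp around the summit. The share with the E2F core falls from 52.8% to 17.9% within the optimal list, and matches to the core centre on the summit.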

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

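The tests of *unc-119* by replicate and by *efl-1* were chosen only after the results were seen.

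The excess of the E2F core continued beyond the optimal list. Of the pooled relaxed regions ranked 2499 to 5000, just below the optimal list, 15.1% (13.8 to 16.6) had the E2F core within 50 bp of the summit, against 4.24% of their flanks (odds ratio 4.02, Fisher's exact test, p = 5.3e-57). It came to notice as a signal outside the optimal list, above its own background. In the last 10000 regions of the list the share was 4.74%, against 3.27% in flanks (odds ratio 1.47, Fisher's exact test, p = 5.7e-10). An excess over flanks was thus present in the weakest regions too, and alone it does not separate EFL-1 signal from background. No biological explanation was tested.

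Ribosomal protein genes were among the most completely bound lists, and most of their peaks lacked the E2F core TTSSCGC. Binding through that core is argued against for the set, since 9.68% of their 62 peaks had it (4.51 to 19.5) against 4.03% of flanks (Fisher's exact test, p = 0.184), while 60.9% (50.4 to 70.5) of the 87 peaks of replication and mitosis genes did. Those 87 peaks were stronger, as the bound genes had median ranks of 279.5 and 366 against 1118. Optimal promoter peaks of like rank, a comparison chosen after the data were seen, had the core in 30.1% (permutation test, adjusted p = 0.0024). Pull-down of heavily used promoters stays open, since no expression values were used here, as does binding by EFL-1 through a partner protein or another sequence, the related TTTCGC (30.6% of these peaks against 4.03% of flanks) among them.

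Mitochondrial DNA held 18 optimal peaks, 1305 per Mb against 24.7 per Mb in the nucleus, and 20 and 19 regions in the top regions of replicates 1 and 2. Background that follows the copy number of mitochondrial DNA and binding there cannot be told apart, because 1 summit had the E2F core, 1000 random sets held 0.126 on average with a 95th percentile of 1, and the mitochondrial genome holds 1 match. No other explanation was tested.

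Inside *unc-119* lay 4 optimal peaks. Extra copies of the *unc-119* fragment of the transgene may account for them, but only 1 of the 4 was in replicate 1's relaxed list (95% upper bound 69.9%), although both replicates came from 1 strain, and 57 of all 2498 optimal peaks (2.28%) were absent from that list. With 4 peaks this stays open. Extra copies of the whole transgene cannot be told apart from this, since *efl-1* had 0 optimal peaks where 0.885 were expected in its 1393 bp of exons at the rate in *unc-119* (exact Poisson p of 0 peaks = 0.413). Binding through an E2F motif also stays open. It had been set beforehand that 0 summits with the core would count against it, and 0 of 4 had it, but the upper bound on 0 of 4 is 49.0%, above the 30.7% of all optimal summits, so that rule was too strict.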

How the results depend on the processing

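Taking optimal peaks found in both replicates' top regions and leaving out mitochondrial peaks were chosen after seeing the data. The excess of the E2F core at summits, the deficit on chromosome X and the promoter share kept their direction and side of the threshold in every alternative run. Their sizes moved. The odds ratio of the core ran from 7.07 with 100 bp either side to 16.5 in the upper 50% of peaks. That of X ran from 0.0966 in the upper 50% of peaks to 0.231 with the relaxed background. Over all main results, 48 alternatives were counted as the same, 15 as moving a value and 1 as ending a call. The 48 include small shifts in counts, such as 11 or 13 lists with more bound genes in place of 12, and values without a threshold, such as rho. The number of lists with fewer bound genes, 2, fell to 1 without replicate 1 and 0 without replicate 2, and to 0 with the upper 50% of peaks, the 500 bp window, the nearest gene only, the relaxed background and peaks in both replicates. It rose to 3 with the 2000 bp window, where sperm genes passed the threshold. None of the intestine or cuticle genes was bound in any alternative, and the share of other genes bound fell from 12.6% to between 7.43% and 12.4% in those that ended a call, save the relaxed background, which left 5 intestine and 8 cuticle genes to test. The counts of overlapping peaks moved with their definition. Of optimal peaks, 64.8% were in replicate 1's top regions and 87.3% in replicate 2's with reciprocal overlap of 50%, 75.5% and 90.9% with summits at most 100 bp apart, 97.9% and 100% in the upper 50% of peaks by signal (1249 peaks by construction), and 82.2% in replicate 1 for promoter peaks. The odds ratio of autosome centres fell to 1.09 (exact p = 0.0971) with genes that have a pooled relaxed summit as background; the cause was not tested. Among named lists, none of those that turned direction was past the threshold in any alternative. RAS and MAP kinase genes went to 12.5% and 12.5% without replicate 1 and without replicate 2, against 12.3% and 11.8% of other genes. Apoptosis genes went to 9.52% without replicate 2 (19.05% without replicate 1), 9.52% with the 500 bp window, 4.76% both with the upper 50% of peaks and with peaks in both replicates, and 21.4% (against 28.2% of other genes) with the relaxed background. The share of the histone list stayed at 12% without replicate 2 and with peaks in both replicates (12% without replicate 1). The share of other genes fell below it there, from 12.6% to 11.8% and 9.90%. With a 2000 bp window the histone share was 18% against 15.3% of other genes, and with the nearest gene only 10% against 9.18%. The cause was not tested. Over the alternatives of single lists and classes, 179 kept their call, 16 lost it (intestine 7, cuticle 6, untranslated or other exons 2, chromatin 1), 3 gained it (transgene parts 2, sperm 1) and 11 turned. Unknown depth limits comparison of signal between replicates, and of the 500 weakest optimal peaks 43.2% were in replicate 1's top regions and 65.6% in replicate 2's.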

Other observations

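All tests in this part were chosen after the data were seen, and they are given as values.

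Gene families named by a shared symbol were tested as well, and some of their genes, of *mcm*, *rsp* and *egg* for example, also stand in the fixed lists. Of 419 families with at least 5 genes, 36 held more bound genes and 22 fewer than the rest at an adjusted p under 0.05 (Fisher's exact test). Nuclear pore genes (*npp*) were bound in 18 of 26 cases, translation initiation genes (*eif*) in 15 of 25, chaperonin genes (*cct*) in 7 of 8, mitochondrial ribosomal genes of the *mrpl* family in 17 of 41, and egg-sperm genes (*egg*) in 6 of 6. The other mitochondrial ribosomal family, *mrps*, was bound in 9 of 29 cases and did not pass the threshold (adjusted p = 0.0521, Fisher's exact test). All 7 bound *mcm* genes and 55.6% of the bound *npp* genes had the E2F core at the peak, while 0 of the 7 bound *rsp* splicing factor genes did. Chemoreceptor families were nearly unbound, with 1 of 193 *str* genes, 5 of 220 *srh* genes and 0 of 109 *srw* genes. C-type lectin genes (*clec*, 6 of 240), nuclear receptor genes (*nhr*, 8 of 269) and collagen genes (*col*, 4 of 156) were also below the rest. Non-coding genes had summits in their windows in 97 of 346 cases for snoRNA (28.03%), 25 of 129 for snRNA (19.4%), 72 of 612 for tRNA (11.8%) and 97 of 15363 for piRNA (0.631%). Such a summit can also lie in the window of a protein-coding gene. These shares therefore do not show binding at promoters of the non-coding genes themselves.

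Sequences at the peaks of ribosomal protein genes were counted. Among 2057 sequences of 6 bases tested within 50 bp of their 62 summits, ACCGTA was present at 41.9% against 1.61% of flanks, GAGACC at 40.3% against 1.61% and ACACTC at 33.9% against 0.806% (adjusted p = 2.5e-09, 5.0e-09 and 7.7e-08, Fisher's exact test). TTTCGC, which resembles the E2F core, was present at 30.6% against 4.03% (exact adjusted p = 2.0e-04) and TCTCGC at 33.9% against 4.03% (exact adjusted p = 3.8e-05). At the 87 peaks of replication and mitosis genes the shares of ACCGTA, GAGACC and ACACTC were 17.2%, 13.8% and 13.8%. At the 1300 optimal promoter peaks without the E2F core they were 15.6%, 18.1% and 9.54%, so these sequences were not confined to ribosomal protein genes. They were 2.64%, 2.64% and 3.08% in the 2724 promoter regions ranked after 20000 in the pooled relaxed list. In the 1713 nuclear optimal peaks without the E2F core, the leading sequences were ACGCGC (16.7% against 1.52% of flanks) and GCGCGC (14.9% against 1.20%). Neither was particular to peaks without the core. ACGCGC was present at 23.4% of optimal promoter peaks with the core and 18.5% of those without it, and GCGCGC at 19.1% and 14.9%. Of 2080 sequences, 454 were more frequent and 531 less frequent than in flanks, so summits and flanks differed widely in sequence.

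The low share of the E2F core at some lists was compared with optimal promoter peaks of like rank, drawn 10000 times. Ribosomal protein peaks had 9.68% against 30.1% (adjusted p = 0.0024, permutation test, from the smallest p the draws can give) and respiratory chain peaks 0 of 14 against 31.96% (adjusted p = 0.0276, permutation test). Meiotic peaks had 10.5% against 32.9% (adjusted p = 0.0876) and DNA replication peaks 67.6% against 47.8% (adjusted p = 0.0768), which did not pass the threshold over the 12 lists by this permutation test. Mitosis peaks had 57.4% against 45.5% (adjusted p = 0.182, permutation test) and oocyte and early embryo peaks 59.4% against 60.5%. No list stood above peaks of like rank past the threshold.

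Around the optimal summits, TTYGAA and the E2F core took different positions. The core was most frequent from -20 to 19 bp, with 9.13 and 9.89 matches per 100 summits in the 2 central bins of 20 bp. TTYGAA had 7.09 and 7.13 there, 11.4 from -60 to -41 bp and 12.4 from 20 to 39 bp. Further out it had 8.41 from -200 to -181 bp and 9.17 from 200 to 219 bp, so it was no more frequent at the centre than in nearby DNA. Peaks on chromosome X were few but carried the core at a share of 34.7% (34 of 98), against 30.8% on autosomes (Fisher's exact test, p = 0.435). The X peaks were weaker, with a median rank of 1812 against 1231.5, and 66.3% against 76.7% lay in promoters. The share of the core falls with rank, and X was not compared with autosomal peaks of like rank. The 500 strongest peaks held 2 of the 98.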
